A study of Caragana korshinskii with 4 samples.

How the data were processed

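RNA was sequenced from Caragana korshinskii seedlings, with 2 control and 2 drought libraries. Per the labels' protocols, 4 pots of 20 seedlings were kept at 23°C with 16 hours of light, drought seedlings went without water for 1 week until they wilted, and RNA of leaves, stems and roots was extracted. Each library pooled RNA of 4 plants and started from 3 µg of total RNA, per the labels' protocols, with messenger RNA picked by its poly(A) tail. How leaves, stems and roots were combined in a library is not given in the sources used here.

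The authors deposited 1 table of the unigenes they called different and a sheet of unigene sequences. Bowtie 0.12.2 and RSEM are named in the submitters' processing notes, with no role or order. The aligner's settings, the assembler, the differential test and its adjustment are not given in the sources used here. The values called read counts per the file headers are a signal per group, which the authors made as a mean over the group's 2 libraries of reads divided by a library size factor, as read from the values. The deposited FPKM values are 1 column per group, per the file headers. The p-value and adjusted p-value columns are the authors' own, per the file headers, and the largest adjusted p in the table is 0.0499. The deposited log2 fold change equals the log2 ratio of the mean normalized read counts within 0.001 for all 410 unigenes above 0 in both groups. It is no number where a group is at 0 (21 unigenes in drought, 9 in control), so log2 fold changes were recomputed from the means. Length in bases is deposited for each unigene, per the file headers, and is the length of the sequence for 407 of 409 sequences used. The sequences of 31 unigenes are not used here. There were 0 further columns of values per sample.

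Reads of each library were recovered from the group means. A mean of 2 libraries scaled by size factors is a sum of whole multiples of 2 steps, and the steps were taken from the smallest values of each column. This gave size factors of 1.22 and 0.971 for drought and 1.07 and 0.833 for control, called the larger and the smaller library of each group. A value was solved when exactly 1 pair of whole read numbers met it within 0.6 units of its last printed digit plus the error of the steps. This held for 439 of 440 drought and 437 of 440 control values. Values shifted at random were solved in 0.191% (drought) and 1.53% (control) of draws, and in 0% of draws below 1000. On simulated means of 2 libraries whose size factors have no small whole-number ratio, 440 of 440 drought-like and 437 of 440 control-like values were solved and all of these were right. With size factors in a ratio of 11 to 9, 120 and 32 of 440 values were solved, all right. The FPKM columns, which the recovery does not use, were checked against the recovered reads. The drought column followed the larger drought library alone (81.2% of 170 unigenes within 10%) and the control column the smaller control library alone (84.5% of 329), in unigenes of at least 500 bases and 100 reads over the group. The depths of 12900000 and 10600000 mapped reads (to the nearest 100000) come from this fit. Recovered reads served to give values without each library and counting intervals. They were not used for a new test of drought against control, so all calls are those of the authors' deposited table.

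Direction was read from the mean normalized read counts. A group at 0 gives a lower bound against a floor of 3 counts over the group, taken at the larger step of that group. Counting intervals are 95% exact (Clopper-Pearson) binomial intervals on the recovered reads. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Where nothing says that libraries came from separate experiments, a spread between them may be technical.

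Gene lists of 71 families in 17 themes, with keywords and protein motifs, were fixed before the data were examined. Members were found by keyword in the deposited descriptions of 364 unigenes. In all, 82 unigenes fell in at least 1 family, 80 lower and 2 higher, and 43 families had no member. Motifs were searched in predicted proteins of at least 50 residues in 6 frames as an alternative. Each theme, and each family with at least 5 members, was tested with Fisher's exact test (two-sided) for its split of higher and lower members against all other described unigenes, with Benjamini-Hochberg adjustment over themes and over families. No enrichment against all genes could be tested, because only called unigenes are listed. Hydrophilin-like proteins were those whose longest predicted protein has above 6% glycine and a mean hydropathy below -1. Length, GC content and the share of the sequence in the longest predicted protein were compared as differences of medians with 100000 permutations (two-sided). On simulated sets, the Fisher tests found a shifted theme in 200 of 200 sets and called 17 of 4000 unshifted themes. Those sets had a larger share of higher unigenes than this list, and the shifted theme was mostly higher. The result therefore does not measure the power of the tests for this list.

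The rule for named genes was fixed before the data were examined. It takes the 5 unigenes at each end of the log2 fold change among those with adjusted p under 0.001 and a value of at least 50 in the higher group. It adds, per theme and direction, up to 2 unigenes with the smallest adjusted p of their families, and the 2 unigenes with the highest value in each group. It gave 33 unigenes, 8 higher and 25 lower. Undescribed unigenes are named by at most 2 identifiers per direction. Alternatives were a stricter adjusted p, a limit on fold or level, 1 unigene per assembly component, motif membership, other hydrophilin limits and pseudocounts of 1 and 10. Leaving out each recovered library, FPKM ratios and the removal of 4 misplaced unigenes were added after the data were seen. Work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.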

Results

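Messenger RNA was sequenced from seedlings of Caragana korshinskii, a drought-hardy legume shrub, grown either with water or without it. Per the labels, the seedlings were 1 month old, and the drought group received no water for 1 week. The series holds 4 libraries, 2 from control and 2 from drought seedlings, and each library pooled RNA of 4 plants. The authors' deposited table lists 440 unigenes (assembled transcripts of an organism used here without a genome) that they called different between the groups, so unigenes they did not call cannot be described. It gives 1 mean normalized read count per group. Reads of the single libraries were recovered from those means (99.8% of the drought and 99.3% of the control values gave 1 solution). The libraries are named here by their size factor, the larger and the smaller of each group, because nothing pairs them with a replicate number. In listed unigenes the recovered reads summed to 100442 in the larger and 42109 in the smaller drought library, and to 337407 in the larger and 323779 in the smaller control library. These sums cover only listed unigenes and are not sequencing depths. The deposited FPKM columns implied 12900000 mapped reads for the larger drought library and 10600000 for the smaller control library. The other depths are unknown.

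The comparison asked which transcripts differ between seedlings left without water and watered seedlings. Most of the called unigenes were lower under drought. The authors' deposited table has 391 unigenes (88.9%) lower and 49 (11.1%) higher under drought. The lower set held histones, tubulins, expansins and pectin-modifying enzymes of growing tissue, ethylene response factors, and enzymes of fermentation such as pyruvate decarboxylase and alcohol dehydrogenase. The higher set held a seed-type lectin, a sugar exporter of the SWEET family, a thaumatin-like defence protein and many transcripts with no description. The median change was 13.2-fold among lower and 18.9-fold among higher unigenes, with unigenes at 0 in a group set at their bound (3 counts over the group).

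**Figure D1:**
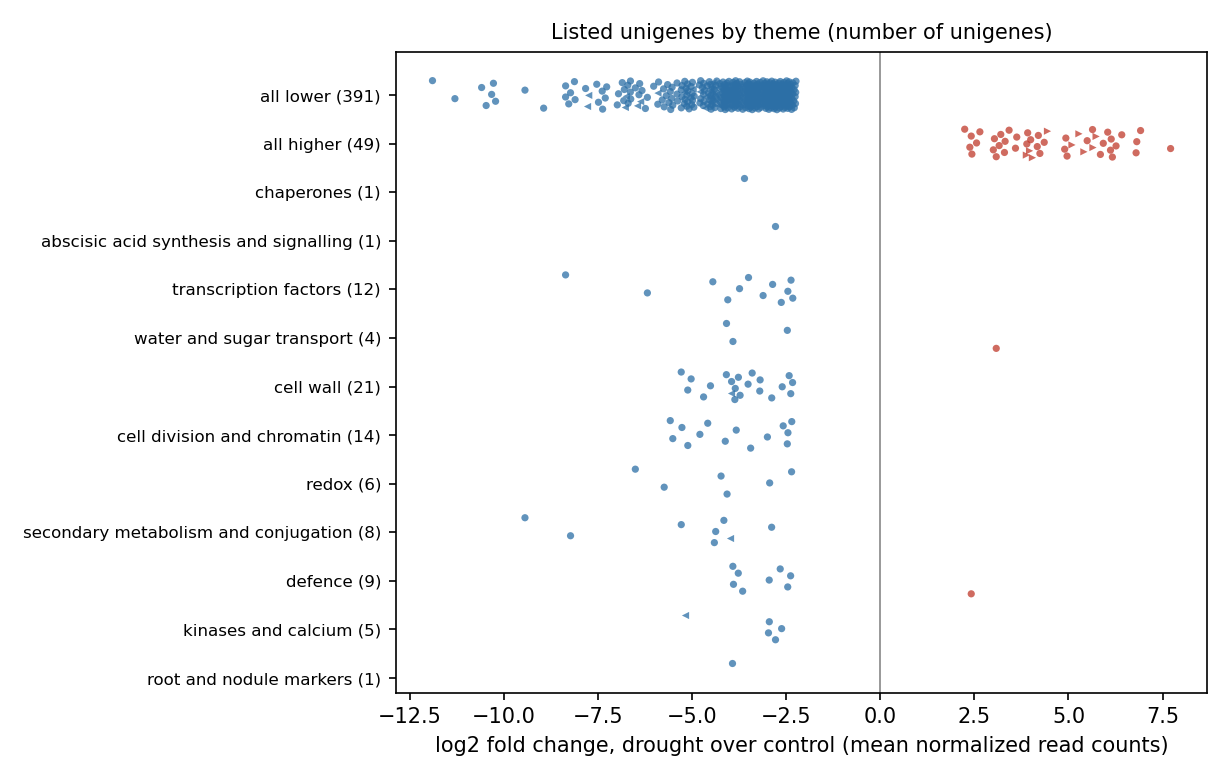
The horizontal axis is the log2 fold change of drought over control, from the authors' mean normalized read counts, and each row is a gene theme with its number of unigenes. Each point is 1 unigene, blue where lower and red where higher under drought (triangles are bounds for unigenes at 0 in 1 group); the 391 lower unigenes extend to -11.91 and the 49 higher ones to 7.71, and of the themes only water and sugar transport and defence have a red point.

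Fermentation and ethylene genes were among those with the smallest adjusted p values of the list. 1-aminocyclopropane-1-carboxylate oxidase 1 (comp63707_c0), which makes ethylene, had an authors' mean of 3999.9 in control and 5.73 in drought in the authors' deposited table, a log2 fold change of -9.45 (adjusted p = 1.44e-23). All 14 of its drought reads lay in the larger drought library, and it had 0 in the smaller, so its log2 fold change was -8.45 without the smaller. A pyruvate decarboxylase fragment (comp63147_c2), of the enzyme that opens ethanol fermentation, fell from 634.9 to 0.409 in the authors' deposited table, which is 1 read over both drought libraries. Its log2 fold change was -10.60, with a counting interval from -15.90 to -8.12, and -9.60 without the smaller drought library. Alcohol dehydrogenase 1 (comp71657_c1), which completes that pathway, had the highest control value of the list, 40351 against 2626 in drought in the authors' deposited table (log2 fold change -3.94, adjusted p = 5.36e-07). Its log2 fold change was -3.51 without the larger and -4.55 without the smaller drought library. Non-symbiotic hemoglobin 1 (comp74445_c0), a haem protein that scavenges nitric oxide, fell from 6232 to 402.5 (log2 fold change -3.95, adjusted p = 8.96e-07 in the authors' deposited table). It was the 1 listed member of the root and nodule markers.

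The transcription factor theme had 12 unigenes by keyword, all lower, 1 of them an acyltransferase matched by accident. Regulators outside its keywords went both ways, and those named here were chosen after their values were seen. LBD41 was lower in 2 unigenes, at log2 fold changes of -6.25 (comp53924_c0) and -4.14 (comp48959_c0), and other regulators such as RADIALIS were lower too. CCA1 (comp62216_c0), a clock gene, was higher at 3.03 and response regulator ARR2 (comp56949_c0), of cytokinin signalling, at 4.35. For ARR2 it was 5.39 without the larger and 3.76 without the smaller control library. RAP2-3 (comp67806_c1), an ethylene response factor of the group that responds to low oxygen, had 1998 in control and 6.05 in drought in the authors' deposited table (log2 fold change -8.37, adjusted p = 2.61e-12). Without the larger drought library its log2 fold change was -9.34, and without the smaller -7.79. A second unigene described as RAP2-3 (comp66647_c0) fell less, from 4358 to 502.1 in the authors' deposited table (log2 fold change -3.12). The homeodomain-leucine zipper gene HOX3 (comp69913_c0) fell by 4.06 on the log2 scale (adjusted p = 0.0010 in the authors' deposited table). The AP2/ERF family had 7 members by description, all lower, of which 1 was that acyltransferase and 1 a B3 domain protein. The other families with members were bHLH (2), WRKY (1) and GRAS (1), and all 4 of these unigenes were lower. NAC, bZIP, R2R3-MYB and heat shock factor keywords matched 0 listed unigenes, but the bZIP motif was found in 1, Ocs element-binding factor 1 (comp61069_c0), at -2.69. Its value was -4.65 without the larger and -1.89 without the smaller drought library.

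Cell wall genes were lower in 21 of 21 described members, with a median log2 fold change of -3.77 (-5.75 without the larger and -3.02 without the smaller drought library). Expansin-B3 (comp67321_c0), of a family that loosens walls in growing cells, fell from 364.6 to 11.2 in the authors' deposited table (log2 fold change -5.03, adjusted p = 3.78e-06). Its log2 fold change was -8.47 without the larger drought library and -4.10 without the smaller. The theme held 6 expansins, 3 cellulose synthase superfamily members, 3 pectinesterases, 2 xyloglucan endotransglucosylases, 1 laccase and 6 unigenes found by the word polygalacturonase. Among the last, polygalacturonase inhibitor 2 (comp56937_c0), a wall protein that blocks the enzyme and not a polygalacturonase, fell from 3300 to 126.9 in the authors' deposited table (log2 fold change -4.70, adjusted p = 3.46e-09). In the 20 members with drought reads, the median share of the drought value in the larger drought library was 87.8%, while 44.1% of the control value lay in the larger control library.

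The cell division and chromatin theme had 14 unigenes by keyword, all lower: 9 core histones, 4 tubulins and 1 mitotic cyclin. Their median log2 fold change was -3.98 (-5.06 without the larger and -3.74 without the smaller drought library). A cyclin that the keywords missed, described as cyclin-SDS-like (comp67645_c1), rose from 15.7 to 233.5 in the authors' deposited table (log2 fold change 3.89, adjusted p = 7.11e-05), and it was chosen after its values were seen. Its log2 fold change was 3.28 without the larger and 4.97 without the smaller control library. Histone H2B.3 (comp40046_c2), a nucleosome component made in dividing cells, fell from 258.3 to 5.64 in the authors' deposited table (log2 fold change -5.52, adjusted p = 5.24e-08). Without the larger drought library its log2 fold change was -6.39, and without the smaller -4.98. Tubulin alpha-1 (comp55503_c0), a microtubule subunit, fell from 8797 to 1097 in the authors' deposited table (log2 fold change -3.00, adjusted p = 0.000756). Its log2 fold change was -5.49 without the larger drought library and -2.14 without the smaller. The median share of the drought value in the larger drought library was 74.3% for this theme.

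**Figure D2:**
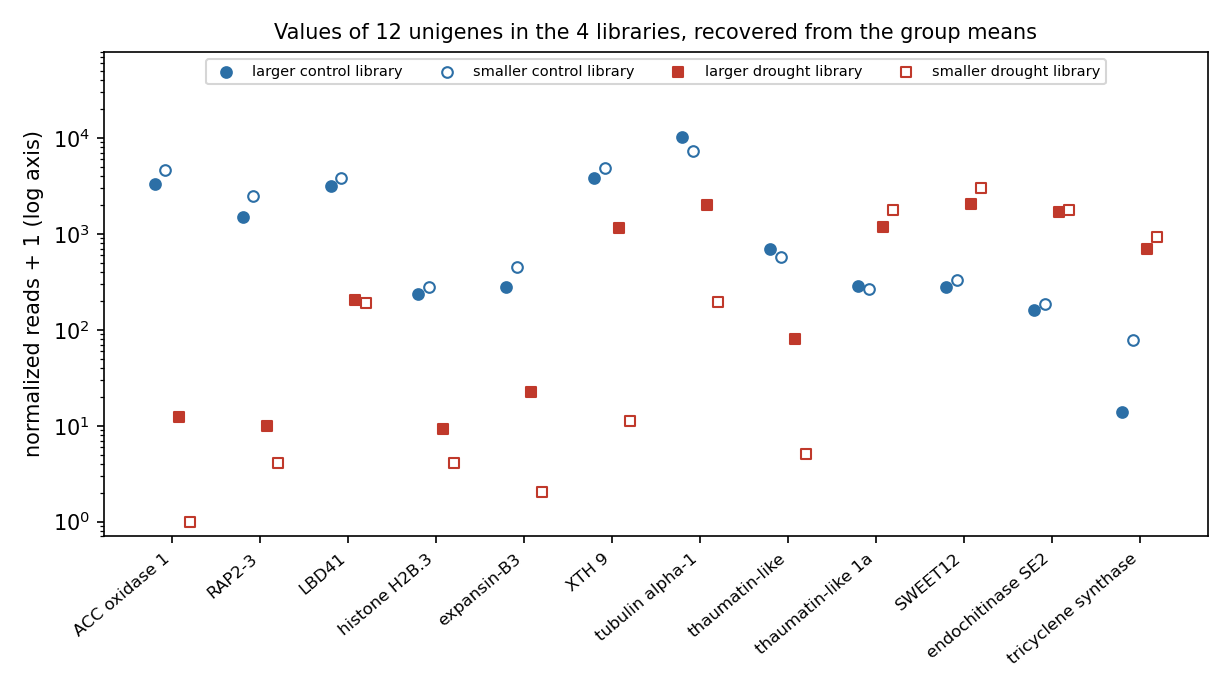
The vertical log axis is normalized reads plus 1 in each library, recovered from the group means, and the horizontal axis lists 12 unigenes, some of them chosen after their values were seen. Among the control (blue circles) and drought libraries (red squares), filled for the larger and open for the smaller library of each group, tubulin alpha-1 and expansin-B3 lie lower in the smaller than in the larger drought library, while SWEET12 is high in both drought libraries.

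Transport and sugar genes went both ways. SWEET12 (comp75927_c0), which exports sucrose from cells, rose from 302.4 to 2556 in the authors' deposited table (log2 fold change 3.08, adjusted p = 0.000372). SWEET17 (comp52843_c0), a fructose carrier of the vacuole membrane, fell from 204.5 to 13.5 in the authors' deposited table (log2 fold change -3.92, adjusted p = 0.000888). The aquaporin PIP-type 7a (comp41230_c0), a water channel of the plasma membrane, fell from 177.8 to 10.4 in the authors' deposited table (log2 fold change -4.09, adjusted p = 0.000193). Without the larger drought library the log2 fold changes of SWEET17 and the aquaporin were -5.63 and -6.43, and without the smaller -3.16 and -3.24. The theme had 4 described members, 3 of them lower.

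Defence genes were lower in 8 of 9 described members. Thaumatin-like protein 1a (comp57280_c0), of an antifungal protein family, rose from 275.9 to 1471 in the authors' deposited table (log2 fold change 2.41, adjusted p = 0.0202). Another thaumatin-like protein (comp59192_c0) fell from 631.6 to 42.2 in the authors' deposited table (log2 fold change -3.91, adjusted p = 1.36e-05). The TMV resistance protein N homologue (comp67959_c0), an immune receptor of the NBS-LRR class, fell from 287.6 to 20.97 in the authors' deposited table (log2 fold change -3.78, adjusted p = 0.000159). Most drought reads of these 2 lay in the larger drought library: their log2 fold changes were -7.26 and -8.13 without it, and -2.98 and -2.81 without the smaller. The 5 beta-1,3-glucanases of the theme, enzymes that cut callose and fungal walls, were all lower.

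The members that keywords placed in the redox, secondary metabolism, kinase, abscisic acid and chaperone themes were all lower. Unigenes of like function that the keywords missed went both ways, and those named here were chosen after their values were seen. Glutaredoxin-C9 (comp62864_c0) was lower at a log2 fold change of -3.81 and mitogen-activated protein kinase kinase 5 (comp68666_c0) at -2.80, which was -4.08 without the larger and -2.14 without the smaller drought library. Higher ones were glutaredoxin-C11 (comp52006_c0) at a log2 fold change of 6.12, phosphoenolpyruvate carboxylase kinase 2 (comp64216_c0) at 3.30 and tricyclene synthase (comp62518_c0), which makes monoterpenes, at 4.17. The fold of glutaredoxin-C11 rests on very few control reads, with 1.07 in control and 73.9 in drought in the authors' deposited table. Without the smaller control library the carboxylase kinase was at 4.14 and the synthase at 5.97, and without the larger they were at 2.77 and 3.39. Redox had 6 of 6 members lower, among them peroxidase 64 (comp52340_c0), with 84.5 in control and 0.924 in drought in the authors' deposited table (2 reads; log2 fold change -6.51, counting interval -9.57 to -4.64, adjusted p = 0.00439), and a log2 fold change of -5.89 without the smaller control library. A glutathione transferase (comp50248_c0), of a detoxifying family, fell by 4.08 on the log2 scale (adjusted p = 3.89e-06 in the authors' deposited table). Secondary metabolism and conjugation had 8 of 8 members lower, and a 4-coumarate-CoA ligase (comp34734_c0), at 24.8 in control and 0 in drought in the authors' deposited table, was at least 16.0-fold lower (adjusted p = 0.0305). Kinases and calcium had 5 of 5 members lower, all receptor-like kinases, with comp69964_c0 at a log2 fold change of -2.97 (adjusted p = 0.00934 in the authors' deposited table). The abscisic acid theme had 1 member, the kinase SAPK2 (comp50788_c0), of a family in which abscisic acid activates some members. It was at -2.80 (adjusted p = 0.0169 in the authors' deposited table). Chaperones had 1 member, a class I small heat shock protein (comp68002_c2), at -3.63 (adjusted p = 0.00780 in the authors' deposited table) with -3.03 without the larger and -4.68 without the smaller drought library.

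Several themes often looked for under drought had no member by keyword. Desiccation protection, osmolytes and reserve sugars, photosynthesis, light stress, proteolysis and nitrogen recycling, and metal binding had 0 described members each. The proteolysis theme covers only papain-like proteases, asparagine synthetase and polyubiquitin; proteases of other families were listed, such as a subtilisin-like protease (comp70905_c0) at -3.30 and aspartic protease in guard cell 1 (comp61741_c0) at -4.27, both lower and both chosen after their values were seen. Without the larger drought library these were -6.01 and -8.64, and without the smaller -2.41 and -3.30. Dehydrins and galactinol synthase are among their families, and the keywords for NCED dioxygenases and PP2C phosphatases of the abscisic acid theme also matched 0 unigenes. The deposited list cannot show whether such genes were unchanged, below its limit or not assembled. The families of the photosynthesis theme, taken as markers of green tissue, had 0 members by keyword. Their levels therefore cannot be set beside those of markers that roots also express. Of the latter, hemoglobin 1 and 3 class III peroxidases were listed, all 4 lower, and 0 metallothioneins.

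The largest falls, among unigenes with adjusted p under 0.001 and a value of at least 50, included unigenes of unknown function. A unigene described from soybean as uncharacterized (comp57007_c0) fell from 6686 to 1.74 in the authors' deposited table, a log2 fold change of -11.91 from 4 drought reads (counting interval -13.78 to -10.55). It was -12.66 without the larger drought and -11.18 without the smaller control library. A unigene matched to an unknown protein of Lotus japonicus (comp62364_c0) fell from 3921 to 1.54 in the authors' deposited table, a log2 fold change of -11.31 from 3 drought reads (counting interval -13.59 to -9.76). It was -10.31 without the larger drought and -10.36 without the smaller control library. All 3 drought reads lay in the smaller drought library, so without that library it had no drought reads. The other end was taken with the same limits, adjusted p under 0.001 and a value of at least 50. Those at 0 in control were ranked at their bound. This end held 4 unigenes with no description and another matched to a protein described as a glyceraldehyde-3-phosphate dehydrogenase fragment. The 5 unigenes at 0 in control with a value of at least 50 ranked below these by bound (the largest bound was at least 53.2-fold higher), so their true rank is unknown. The unigene matched to the dehydrogenase (comp69169_c0), a glycolytic enzyme, is 2488 bases long. It rose from 2.46 to 189.2 in the authors' deposited table (log2 fold change 6.26, adjusted p = 0.000427). Its log2 fold change was 7.30 without the larger and 5.67 without the smaller control library. Of the undescribed ones, comp67645_c0 had 97.7 in drought and 0.465 in control (1 read) in the authors' deposited table, a log2 fold change of 7.71 with a counting interval from 5.22 to 13.02. Another, comp77641_c0, rose from 5.12 to 569.1 (log2 fold change 6.80, adjusted p = 1.33e-12 in the authors' deposited table). Without the smaller control library these 2 log2 fold changes were 6.71 and 5.80, and without the larger both had 0 control reads. The cyclin-SDS-like unigene given above (comp67645_c1) is of the same assembly component as comp67645_c0 and rose less, at a log2 fold change of 3.89.

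The 2 highest values in drought belonged to a lectin and a vitamin enzyme, and the 2 highest in control to alcohol dehydrogenase and that vitamin enzyme. A lectin described as seed agglutinin 2 (comp67704_c0), a sugar-binding storage protein of legumes, rose from 646.2 to 12208 in the authors' deposited table (log2 fold change 4.24, adjusted p = 2.85e-08). Its control reads were uneven, 108 in the larger and 993 in the smaller control library, so its log2 fold change was 3.36 without the larger and 6.92 without the smaller. Thiamine thiazole synthase 2 (comp63258_c0), of vitamin B1 synthesis, fell from 34979 to 7132 in the authors' deposited table (log2 fold change -2.29, adjusted p = 0.0410). Its log2 fold change was -4.07 without the larger drought library and -1.52 without the smaller.

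**Figure D3:**
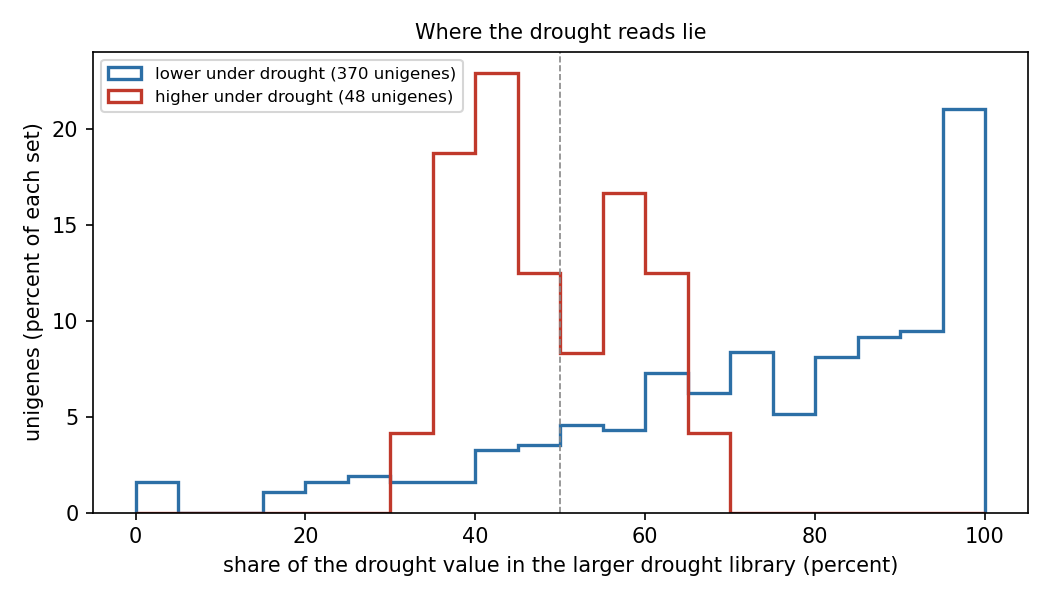
The horizontal axis is the share of the drought value that lay in the larger drought library, in percent, and the vertical axis the percent of unigenes in each set, with 370 lower (blue) and 48 higher (red) unigenes. Against the dashed line of equal shares, the median was 79.1% for lower and 47.3% for higher unigenes.

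No theme of the 11 with a member passed the test for a split unlike that of the other described unigenes. The smallest p of the two-sided Fisher's exact tests was 0.249, for water and sugar transport, and the smallest Benjamini-Hochberg adjusted p was 1. The 7 families with at least 5 members, all lower, gave p = 1 in each exact test. With 25 higher among 364 described unigenes, a theme whose members are all lower cannot stand apart from the rest of this list, so these tests say little about it. Proteins of the hydrophilin kind, rich in glycine and strongly hydrophilic, were predicted for 1 higher and 4 lower unigenes (Fisher's exact test, two-sided, p = 0.464).

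Higher unigenes held less coding sequence than lower ones. The longest predicted protein covered a median of 52.4% of the sequence in 47 higher and 68.7% in 362 lower unigenes, a difference of -16.3 percentage points (permutation test, two-sided, p = 0.000430). No description was given for 49.0% of the higher and 13.3% of the lower unigenes (Fisher's exact test, two-sided, p = 3.79e-08, chosen after the values were seen). Median lengths were 980.0 and 1050.5 bases (p = 0.695) and median GC contents 40.96% and 41.5% (p = 0.445, both permutation tests, two-sided). No adjusted p here comes from a new test of the groups, and intervals cover counting error only, not the spread between seedlings.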

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

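Leaving out libraries, FPKM ratios and the removal of misplaced unigenes were chosen after the data were seen. At adjusted p under 0.001 the counts dropped to 21 higher and 146 lower unigenes, because fewer pass. They stayed within 1.5 times of 49 and 391 under the limit on level (39 and 362) and with 1 unigene per component (47 and 366). The limit on fold, an absolute log2 fold change of at least 2, left 49 and 391. It could remove no unigene, because the smallest in each direction was 2.24, so it tests nothing. Unigenes with a log2 fold change of at least 2 on their side numbered 48 to 49 higher and 340 to 391 lower when 1 recovered library was left out, lowest without the smaller drought library, and 47 and 307 by FPKM ratio. Themes and families past adjusted p 0.05 numbered 0 under every alternative run, of which the limit on fold left the list unchanged. Family splits by motif gave no value, since no family had 5 members by motif. Motifs were found in 29 unigenes in 6 frames and in 29 in the longest frame, and in 1 with reversed proteins. The hydrophilin split (exact test) turned direction, from 1 higher and 4 lower to 0 and 2 (p = 1) at adjusted p under 0.001 and to 0 and 4 (p = 1) at values of at least 50; p was 0.374 to 0.471 under the other limits. At values of at least 50 the length difference turned from -70.5 to 42 bases (permutation p = 0.935), the GC difference grew from -0.590 to -2.01 percentage points (p = 0.0208), and the protein share difference was -16.4 (p = 0.00155); the cause was not tested. Of the 32 named unigenes above 0 in both groups, 9 moved over 1.5-fold with a pseudocount of 1 and 19 with 10, none to the other direction. Without the larger drought library 13 of 28 did so, and without the smaller 13 of 30. Without the larger and smaller control library it was 3 of 27 and 8 of 29. Named unigenes with 0 reads left in a group, or with unsolved reads, are not in these counts. Among them were comp63707_c0 without the larger drought library and comp67645_c0 without the larger control library. The counts therefore understate how far the named folds depend on 1 library. Depth limits most the folds that rest on 1 to 4 reads. No paired analysis was possible because the deposited group means carry no replicate numbers. Other normalizations, and a model with libraries left out, were not run, because values per library are only recovered here.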

Other observations

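All tests and gene groups in this part were chosen after the result was seen. Of all described unigenes in the list, 339 of 364 were lower, so a group with all members lower says little by itself. Genes of nitrate uptake and reduction were lower in 8 of 8 unigenes (7 assembly components). In the authors' deposited table, nitrate reductase (comp75901_c0), the entry step of nitrate assimilation, fell from 6446 to 568.5. Ferredoxin-nitrite reductase (comp69243_c0) fell there from 10604 to 1539, a log2 fold change of -2.78 (-3.73 without the larger and -2.22 without the smaller drought library). A list of DNA replication and mitosis genes, which leaves out the cyclin-SDS-like unigene that rose, was lower in 18 of 18, among them thymidine kinase (comp56950_c0), which salvages thymidine, at a log2 fold change of -6.64, and the cytokinesis syntaxin KNOLLE (comp69142_c0) at -3.78. Their 6 and 22 drought reads all lay in the larger drought library, and without the smaller the values were -5.64 and -2.78. All 7 pectate lyases (6 assembly components), 3 fasciclin-like arabinogalactan proteins and 3 gibberellin-regulated proteins were lower. Their median log2 fold changes were -4.20, -2.89 and -3.01. A median of 97.6%, 90.8% and 96.6% of their drought value lay in the larger drought library. Without it the medians were -7.63, -5.01 and -6.91, and without the smaller -3.26, -2.23 and -2.06. Of 8 lipid-transfer proteins, 7 were lower and 1 (comp35632_c0) was higher at 3.00 (2.15 without the larger and 5.33 without the smaller control library).

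Defence-related unigenes that the keywords missed went both ways. Pathogenesis-related protein PR-1 (comp66294_c0) was lower at a log2 fold change of -4.70 (-9.54 without the larger and -3.72 without the smaller drought library). An osmotin-like protein (comp71725_c0) was at -3.84 (-4.62 without the larger and -3.35 without the smaller drought library). Other PR-1 unigenes and a defensin-like one were lower too. Acidic endochitinases, enzymes that cut chitin, were higher in 2 unigenes (3.32 for comp67875_c0 and 2.64 for comp24977_c0) and lower in 1 (-2.70 for comp70100_c0). The value of comp24977_c0 was 2.10 without the larger and 3.52 without the smaller control library. It was 2.98 without the larger and 2.21 without the smaller drought library. That of comp70100_c0 was -8.33 without the larger and -1.72 without the smaller drought library. Of 3 lectins described as seed agglutinin or seed lectin, 1 was higher and 2 lower, at -2.36 and -2.25. The 2 lower ones are of the same assembly component, so they may not be 2 genes. Without the larger drought library the lower ones were at -3.09 and -2.97, and without the smaller at -1.87 and -1.77. Stress-induced protein SAM22 (comp68053_c0), a PR-10 protein found by its motif, was higher at 2.24. Proteins of fungi, an oomycete or an amoeba described 5 unigenes, 4 lower and 1 higher (Fisher's exact test, two-sided, p = 0.301).

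Most drought reads of the lower unigenes came from 1 library. The larger drought library held a median of 79.1% of the drought value in 370 lower unigenes and 47.3% in 48 higher ones. The difference was 31.8 percentage points (permutation p = 1e-05, two-sided, the smallest the permutations can give). If 1 size factor were wrong, all unigenes would shift alike, so the difference argues against it as the only cause. The test cannot exclude it, because both sets were called from these same drought values and unigenes were permuted as if independent. An error in the recovery is argued against by the drought FPKM column, which followed the larger library's reads with a median residual of 0.0253 on the log2 scale. Control RNA carried over would add 1 fraction of every control value, but at the 5th percentile of 94 abundant lower unigenes the larger drought library held 0.299% of the control mean, against a median of 16.3%. The plants pooled in the 2 drought libraries may have differed in tissue share or in how far they had dried, which was not tested.

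Fold changes from the FPKM columns were mostly smaller than those from the mean read counts: the FPKM ratio minus the read count ratio had a median of 0.86 on the log2 scale in lower and -0.18 in higher unigenes (0.82 over all 396 above 0 on both scales, which kept their direction). The FPKM ratio followed the ratio of the larger drought and smaller control library with a median residual of 0.00158, against 0.264 for the group means, in line with each FPKM column holding 1 library and not the group. Scaling by library totals in place of size factors shifts all unigenes by 0.272, which is not the whole cause. No biological explanation was tested.

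Genes linked to low oxygen were lower under drought. The 18 unigenes of pyruvate decarboxylase, alcohol dehydrogenase 1, 2-aminoethanethiol dioxygenase, LBD41, RAP2-3 and related descriptions had a median log2 fold change of -5.31. They came from 15 assembly components, so some may be parts of the same gene. The median was -6.03 without the larger and -5.15 without the smaller drought library. These unigenes were picked after their values were seen, so the size of their changes says nothing against other unigenes. The shift between scalings, 0.272, is too small to be the cause of these changes. Their control value lay in both control libraries (median 45.7% in the larger), which argues against 1 stressed control library. Reads from another organism stay open: 0 members were described from a fungus, oomycete or amoeba, but the list was picked by plant descriptions, so this count decides nothing. Induction in the control seedlings and lowering by drought cannot be told apart with 2 groups of seedlings, since no other condition shows the usual level.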
